A study of Homo sapiens with 24 samples.

How the data were processed

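RNA was measured in 24 libraries, 2 per group in 12 groups, untreated or treated with 10 µM glyceollin I for 6, 12 or 24 h, from the lines MDA-MB-468, MCF7 and MCF7-LTED. Per the labels' protocols, MCF7 and MDA-MB-468 grew in RPMI medium with 10% fetal bovine serum and MCF7-LTED in the same without phenol red and with 4% charcoal-stripped serum, and RNA was purified with RNeasy Mini kits and made into libraries with a TruSeq Stranded mRNA kit. STAR 2.6.0b, featureCounts 2.0.0, DESeq2 1.24.0 and hg38 are named, per the submitters' processing notes, without the strand setting, annotation release or read filters. Raw counts per gene were deposited as 1 table per line with 58735 gene IDs, per the file headers, and had not been normalized by the authors. A second deposited table per line holds normalized signal, which equals the raw counts divided by 1 factor per library for genes with at least 7 reads, and it was used only to check the raw counts. The authors deposited, for each line and time, log2 fold changes with standard errors, and p-values with adjusted p-values, in columns named as DESeq2 writes them, per the file headers. The columns give the line and time of each library and a number that does not match the replicate numbers of the titles, so libraries are called by group and column number. All 24 columns of counts were used.

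Library totals ran from 16484123 to 31516186 counts. A count of 0 in a library allows up to 3 counts, 0.0952 to 0.182 CPM, which covers counting error and not the spread between cultures. Gene symbols and positions came from GENCODE 29, which held 58735 of the gene IDs. Each line was fitted apart with edgeR 4.0.16 in R 4.3.3 on raw counts, with trimmed mean of M-values (TMM) factors, filterByExpr by group, group means and a robust quasi-likelihood fit, and each time was tested against the control and 24 h against 6 h. A fit of all 24 libraries gave the differences between lines in the response to 6, 12 and 24 h and between untreated MCF7-LTED and MCF7. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested, 16506 in MCF7, 16017 in MCF7-LTED, 15874 in MDA-MB-468 and 18669 in the joint fit. CPM were computed on effective library sizes. The square root of the common dispersion was 9.54%, 22.9%, 10.3% and 15.4% in these fits.

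Gene lists, 31 in number, were written from general knowledge: estrogen-induced genes, receptors and identity genes, DNA replication, mitosis, p53 targets, unfolded protein response, integrated stress response, NRF2 targets, aryl hydrocarbon receptor targets, cholesterol synthesis, fatty acid synthesis, LXR targets, hypoxia, heat shock, interferon, NF-kB, immediate early, FOXO and receptor feedback, TGF-beta, apoptosis, autophagy, ribosome biogenesis, histones, metallothioneins, ribosomal proteins, mitochondrial genome, oxidative phosphorylation, stroma, leukocyte, luminal and basal markers. Genes may sit on several lists. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on voom values with an inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists of a comparison. Where the call of camera was lost with the estimated correlation, that adjusted p is printed beside it, and elsewhere in the report the call held with both. The named genes are, per line, the 8 highest and 8 lowest at 24 h and the 4 highest and 4 lowest at 6 h among genes past the test with mean log2 CPM of at least 3 and treated libraries beyond both controls. They further include the 5 highest and 5 lowest differences for each pair of lines, the 6 highest and 6 lowest of untreated MCF7-LTED against MCF7, up to 4 members of each list with the smallest adjusted p, and 13 genes named whatever their result. The lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined, except the fits without 1 MCF7-LTED library, the block on column number and the tests named as later choices in the closing parts.

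The fits were tested on simulated counts with 200 changed genes. At 24 h against control, 1.5-fold, 2-fold and 4-fold changes were recovered at 46.3%, 83.6% and 98.5% in MCF7, 0%, 7.46% and 81.8% in MCF7-LTED and 46.3%, 89.6% and 98.5% in MDA-MB-468, with 13 of 16094, 3 of 15659 and 10 of 15475 unchanged genes called. For the difference between MDA-MB-468 and MCF7 the shares were 0%, 22.4% and 80.3%, with 4 of 18350 unchanged genes called. A shift of -0.5 log2 in the replication list was called in each line by camera at both correlations and by fry. Of other lists, fry called 1 of 29 in MDA-MB-468. Correlated genes and wider responses were not simulated and stay untested. The alternatives were DESeq2 1.42.0, relative log expression factors, library totals alone, no filter on low counts, a mean of at least 50 counts, the compared libraries only, leaving out each library in turn, a block on column number, and the authors' adjusted p-values. Further tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. With 2 libraries per group, no test over other splits was possible. The strand setting is not stated, so antisense and overlapping genes are uncertain.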

Results

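Raw counts of 58735 genes covered 24 RNA-seq libraries from 3 human breast cancer cell lines exposed to the soybean phytoalexin glyceollin I at 10 µM. The lines were MCF7, which carries estrogen receptor alpha, MCF7-LTED, its derivative kept under long-term estrogen deprivation, and the basal-like line MDA-MB-468, which lacks the receptor. Libraries were made from untreated control cells and after 6, 12 and 24 h, with 2 per group, and the titles call them biological replicates. The values are counts of messenger RNA reads, so no protein level, receptor activity or cell growth was measured. The untreated cells of a line served as the control for all 3 times, and the labels give neither a vehicle control nor the hour at which the control cells were collected. Time in culture and the carrier of the compound therefore cannot be separated from the compound. The MCF7-LTED cells were grown in another medium and serum than MCF7, so the line and its medium cannot be told apart. Levels are in CPM, given as mean ± SD (n = 2), and positions are on GRCh38. Changes are log2 fold changes against the control unless another comparison is named, with the standard error (SE) of the fit where it is given.

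In MCF7 cells, 24 h of glyceollin I raised mRNA of a xenobiotic-metabolizing enzyme, metal-binding proteins and stress-induced genes. The largest of the named rises was that of CYP1A1 (ENSG00000140465, chromosome 15, 74719542 to 74725610), a cytochrome P450 induced through the aryl hydrocarbon receptor, from 0.904 ± 0.33 to 114 ± 13.6 CPM (log2 fold change 6.95, SE 0.192, adjusted p = 1.5e-10). The metallothionein MT1X (ENSG00000187193, chromosome 16, 56682424 to 56684196) went from 1.22 ± 0.169 to 62.7 ± 20.9 CPM (5.68, SE 0.253), and which metallothionein its reads came from is uncertain because the family is nearly identical in sequence. The stress cytokine GDF15 (ENSG00000130513, chromosome 19, 18374731 to 18389176) rose from 30.1 ± 2.41 to 538 ± 21.9 CPM (4.16, SE 0.118) and the polyamine-acetylating enzyme SAT1 (ENSG00000130066, chromosome X, 23783173 to 23786226) from 27.4 ± 3.79 to 316 ± 68.5 CPM (3.52). The hair keratins KRT81 (ENSG00000205426, chromosome 12, 52285913 to 52291534) and KRT86 (ENSG00000170442, chromosome 12, 52249300 to 52309163) had log2 fold changes of 4.12 and 3.81, but they overlap and are nearly identical, so which of them rose is uncertain. The Rho-family GTPase RND1 (ENSG00000172602, chromosome 12, 48857145 to 48865898, 3.95) and the neurotrophin receptor NGFR (ENSG00000064300, chromosome 17, 49495293 to 49515017, 3.85) rose as well.

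Among MCF7 genes with a mean of at least 3 log2 CPM, CXCL12 and SFXN2 fell furthest at 24 h. The chemokine CXCL12 (ENSG00000107562, chromosome 10, 44370165 to 44386493), itself estrogen-responsive, went from 51.8 ± 0.52 to 4.87 ± 0.229 CPM (log2 fold change -3.41, SE 0.147, adjusted p = 9.4e-09). The mitochondrial carrier SFXN2 (ENSG00000156398, chromosome 10, 102714538 to 102743492) went from 121 ± 0.824 to 13.8 ± 2.4 CPM (-3.14, SE 0.128). The neuropeptide Y receptor NPY1R (ENSG00000164128, chromosome 4, 163323961 to 163344832, -2.89), the calcitonin receptor CALCR (ENSG00000004948, chromosome 7, 93424487 to 93574730, -2.68) and the AP-1 subunit FOS (ENSG00000170345, chromosome 14, 75278774 to 75282230, -2.63) fell too. So did the fatty acid elongase ELOVL2 (ENSG00000197977, chromosome 6, 10980759 to 11044314, -2.48), the sulfate transporter SLC26A2 (ENSG00000155850, chromosome 5, 149960737 to 149993455, -2.44) and the mitochondrial ATP synthase subunit MT-ATP8 (ENSG00000228253, the mitochondrial chromosome, 8366 to 8572, -2.42). Of 16506 genes tested, 8031 passed, 4052 higher and 3979 lower, and 1324 and 1473 of these changed at least 2-fold. The balance of rises and falls depended on scaling, since 50.5% of the changed genes were higher with trimmed-mean scaling and 37.1% with library totals.

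**Figure D1:**
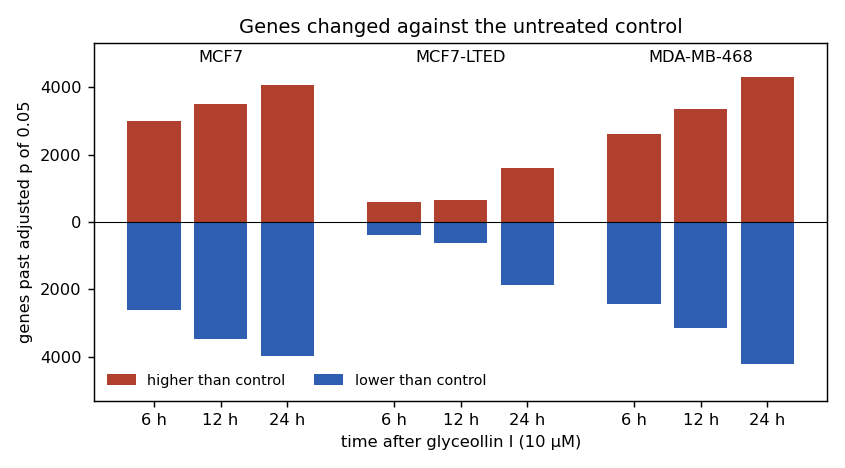
Genes with an edgeR adjusted p under 0.05 against the untreated control in each line at 6, 12 and 24 h, higher above the line and lower below it. Each group held 2 libraries.

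Estrogen targets, and by 24 h the estrogen receptor gene, were lower in treated MCF7 cells. The progesterone receptor PGR, a classical estrogen target, fell from 84.9 ± 1.94 to 17.9 ± 1.8 CPM at 24 h (log2 fold change -2.25, adjusted p = 2.1e-08), and the receptor gene ESR1 from 349 ± 22.6 to 195 ± 38.8 CPM (-0.84). The estrogen-induced genes GREB1 (-0.81) and PDZK1 (-3.17) fell as well, while CCND1 (0.16, adjusted p = 0.242), which encodes cyclin D1, did not pass. The estrogen-induced secreted peptide TFF1 fell by less (-0.43, adjusted p = 0.00824), and this call was lost when only the control and 24 h libraries were fitted (adjusted p = 0.0517, 0.000495 to 0.0775 over the alternatives). Among genes induced through the estrogen receptor, 9 of 50 rose and 31 fell (9 and 33 adjusted over the list alone, camera adjusted p = 8e-06). Luminal line markers went the same way, and 2 of 15 rose and 9 fell (2 and 10 adjusted over the list alone, camera adjusted p = 0.000738). Losses included the secreted protein AGR2 (-1.497), the receptor tyrosine kinase RET (-0.91) and the acetyltransferase NAT1 (-1.62). Basal line markers went up, and 7 of 10 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.00137). Members included keratin KRT17 (2.56) and lipocalin LCN2 (2.34). The list of receptors and identity genes did not shift as a whole, as 10 of 27 rose and 9 fell (10 and 12 adjusted over the list alone, camera adjusted p = 0.65). GPER1, a G protein-coupled estrogen receptor, fell (-2.38) and the insulin receptor INSR rose (1.39).

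Genes of DNA replication fell widely in MCF7 at 24 h. Of the replication and E2F targets, 1 of 55 rose and 42 fell (1 and 42 adjusted over the list alone, camera adjusted p = 1.19e-14). Among them were dihydrofolate reductase DHFR (-1.78), flap endonuclease FEN1 (-1.68), thymidine kinase TK1 (-1.55) and the helicase subunit MCM3 (-1.43). Of G2/M and mitosis genes, 6 of 54 rose and 18 fell (6 and 18 adjusted over the list alone, camera adjusted p = 0.0406, adjusted p = 0.283 with an estimated correlation), with the spindle gene ASPM (-1.55) and the kinesin KIF11 (-0.87) down and the phosphatase CDC25B (0.98) up. The proliferation marker MKI67 did not pass (0.00284, adjusted p = 0.993). Among direct p53 targets, 21 of 34 rose and 1 fell (23 and 2 adjusted over the list alone, camera adjusted p = 2.18e-06, adjusted p = 0.063 with an estimated correlation), with the cell cycle inhibitor CDKN1A (2.16), the BH3-only gene BBC3 (2.28) and the growth arrest gene GADD45A (2.61) higher. Of apoptosis regulators, 14 of 31 rose and 6 fell (14 and 7 adjusted over the list alone, camera adjusted p = 0.0995), and the estrogen-dependent survival gene BCL2 fell (-2.304) while MCL1 rose (1.05). Ribosome biogenesis and MYC target genes declined, and 4 of 38 rose and 18 fell (4 and 19 adjusted over the list alone, camera adjusted p = 0.000744). Members included the nucleolar genes NOP56 (-1.09) and NOP58 (-1.08), although MYC itself rose (0.55).

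Stress and detoxification programs rose in MCF7 at 24 h. Of integrated stress response genes, 33 of 37 rose and 1 fell (34 and 1 adjusted over the list alone, camera adjusted p = 1.16e-13). The transcription factor DDIT3 went from 6.53 ± 0.259 to 60.9 ± 14.7 CPM (3.22) and the amino acid transporter subunit SLC3A2 rose (1.95). Of unfolded protein response genes, 18 of 27 rose and 2 fell (18 and 3 adjusted over the list alone, camera adjusted p = 4.61e-05). Among them were the ER stress sensor ERN1 (1.33) and the ER-associated degradation gene HERPUD1 (1.25). Of NRF2 targets, 23 of 34 rose and 2 fell (24 and 2 adjusted over the list alone, camera adjusted p = 4.87e-07), with heme oxygenase HMOX1 (2.19), the cystine transporter SLC7A11 (2.65) and the quinone reductase NQO1 (0.66) higher. Of aryl hydrocarbon receptor targets, 11 of 14 rose and none fell (12 adjusted over the list alone, camera adjusted p = 1.8e-06). Members included CYP1B1 (2.24) and the receptor's feedback gene TIPARP (0.97). Of metallothionein and zinc response genes, 4 of 5 rose and none fell (4 adjusted over the list alone, camera adjusted p = 0.000103), and the zinc exporter SLC30A1 (1.48), which has no close sequence relative in that family, was among them. Of heat shock genes, 4 of 19 rose and 8 fell (4 and 8 adjusted over the list alone, camera adjusted p = 0.0995). The constitutive chaperone HSPA8 fell (-1.003). Of autophagy and lysosome genes, 26 of 40 rose and 6 fell (26 and 6 adjusted over the list alone, camera adjusted p = 6.66e-05), and the lysosome regulator TFEB (2.32) and the Rag GTPase RRAGD (3.02) rose. Of FOXO and receptor feedback genes, 24 of 32 rose and 3 fell (24 and 3 adjusted over the list alone, camera adjusted p = 4.87e-07). Among them was the PI3K inhibitor PIK3IP1 (2.24).

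Cholesterol and fatty acid genes rose in MCF7 as well. Of cholesterol synthesis and uptake genes, 17 of 25 rose and 2 fell (17 and 2 adjusted over the list alone, camera adjusted p = 1.8e-06), with the sterol synthesis enzymes HMGCS1 (1.81), FDFT1 (1.31) and MSMO1 (1.77) higher. Of fatty acid synthesis genes, 16 of 22 rose and 1 fell (16 and 2 adjusted over the list alone, camera adjusted p = 3.07e-05). Members included the desaturase SCD (2.24) and the acetyl-CoA synthetase ACSS2 (2.29). Of cholesterol efflux and LXR genes, 5 of 12 rose and 3 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.41). Of hypoxia and glycolysis genes, 16 of 35 rose and 8 fell (16 and 8 adjusted over the list alone, camera adjusted p = 0.0232, adjusted p = 0.077 with an estimated correlation). These included the growth factor VEGFA (1.78). Of NF-kB and inflammatory genes, 12 of 18 rose and 2 fell (12 and 2 adjusted over the list alone, camera adjusted p = 0.000141). Among them were the adhesion molecule ICAM1 (3.38) and the NF-kB subunit RELB (2.35). Of immediate early and AP-1 genes, 26 of 36 rose and 4 fell (26 and 4 adjusted over the list alone, camera adjusted p = 7.04e-07), and ATF3 (2.702) and JUN (1.29) rose where FOS fell. Of TGF-beta and mesenchymal transition genes, 19 of 30 rose and 3 fell (19 and 4 adjusted over the list alone, camera adjusted p = 0.000199, adjusted p = 0.0557 with an estimated correlation). Members included the matrix gene TGFBI (2.27). Of interferon-stimulated genes, 15 of 37 rose and 5 fell (15 and 7 adjusted over the list alone, camera adjusted p = 0.22), and their median log2 fold change moved from 0.0139 to -0.12 with library totals.

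Gene groups whose read counts depend on library preparation were read apart. Of genes of the mitochondrial genome in MCF7 at 24 h, 1 of 13 rose and 8 fell (1 and 8 adjusted over the list alone, camera adjusted p = 2.62e-05, adjusted p = 0.255 with an estimated correlation), among them MT-CO3 (-2.298), a cytochrome oxidase subunit, and MT-ND2 (-2.06), a complex I subunit. Of nuclear genes of oxidative phosphorylation, 4 of 44 rose and 6 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.924), their median log2 fold change moved from 0.0488 to -0.0889 with library totals, and the test leaned downward while the median stood above 0. Of ribosomal protein genes, 17 of 55 rose and none fell (7 adjusted over the list alone, camera adjusted p = 8.3e-05, adjusted p = 0.583 with an estimated correlation). These included RPL12 (0.61). Of replication-dependent histone genes, whose transcripts mostly lack the poly(A) tail that the library kit selects, 8 of 22 rose and 6 fell (9 and 6 adjusted over the list alone, camera adjusted p = 0.142), with linker histone H1-4 (4.702) and H2BC21 (2.17) higher, and reads of near-identical histone copies may be shared.

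The response of MCF7 was already broad at 6 h. CYP1A1 reached 266 ± 3.69 CPM (log2 fold change 8.17, SE 0.195, adjusted p = 4.74e-11), MT1X stood at 5.49 and NGFR at 3.72. The adhesion molecule ICAM1 (ENSG00000090339, chromosome 19, 10270835 to 10286615) rose (3.35), and the aryl hydrocarbon receptor repressor AHRR (1.85) and CYP1B1 (2.68) rose with it. C1orf226 (ENSG00000239887, chromosome 1, 162366908 to 162386818, -2.21), CXCL12 (-2.102), CALCR (-1.93) and the transcription factor SOX2 (ENSG00000181449, chromosome 3, 181711924 to 181714436, -1.66) fell furthest among genes with a mean of at least 3 log2 CPM. PGR had fallen by 6 h (-1.11), while ESR1 did not pass at 6 h (-0.00524, adjusted p = 0.98) or at 12 h (-0.29, adjusted p = 0.0809). Of estrogen-induced genes at 6 h, 6 of 50 rose and 26 fell (7 and 30 adjusted over the list alone, camera adjusted p = 7.34e-07). Of replication genes, 37 of 55 fell and none rose (38 adjusted over the list alone, camera adjusted p = 1.38e-13). Of immediate early genes, 30 of 36 rose and 2 fell (32 and 2 adjusted over the list alone, camera adjusted p = 4.51e-14). Among them were NR4A1 (2.69) and EGR1 (2.26). Of NF-kB genes, 12 of 18 rose and none fell (12 adjusted over the list alone, camera adjusted p = 1.28e-07). Members included RELB (3.04) and the inhibitor TNFAIP3 (3.08). Of cholesterol genes, 16 of 25 rose and 1 fell (16 and 2 adjusted over the list alone, camera adjusted p = 2.6e-07). At 6 h 5593 genes passed (2992 higher, 2601 lower) and at 12 h 6946 (3487 higher, 3459 lower), with 53.5% and 50.2% higher (44.4% and 42.5% with library totals). The counts were as low as 2733 without MCF7 6 h column-2 and 4222 without MCF7 12 h column-2. At 12 h CYP1A1 stood at 132 ± 10.8 CPM (7.16). Of replication genes, 37 of 55 fell and none rose (44 and 1 adjusted over the list alone, camera adjusted p = 1.84e-12).

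Between 6 and 24 h the stress programs of MCF7 grew and its replication genes went down further. Set directly against 6 h, 3546 genes differed at 24 h, 1779 higher and 1767 lower (50.2% higher, 34.1% with library totals). The count ran from 953 without MCF7 6 h column-3 to 4561 without MCF7 24 h column-2. Integrated stress response genes were higher at 24 h than at 6 h, as 25 of 37 were higher and none was lower (28 adjusted over the list alone, camera adjusted p = 1.61e-16). DDIT3 stood at 16.6 CPM at 6 h and 60.9 CPM at 24 h. Of NRF2 targets, 13 of 34 were higher and none was lower (17 adjusted over the list alone, camera adjusted p = 7.11e-07). Of replication genes, 1 of 55 was higher and 25 were lower (3 and 31 adjusted over the list alone, camera adjusted p = 3.09e-06). Of ribosomal protein genes, 34 of 55 were higher and none was lower (50 adjusted over the list alone, camera adjusted p = 9.23e-15, adjusted p = 0.43 with an estimated correlation).

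**Figure D2:**
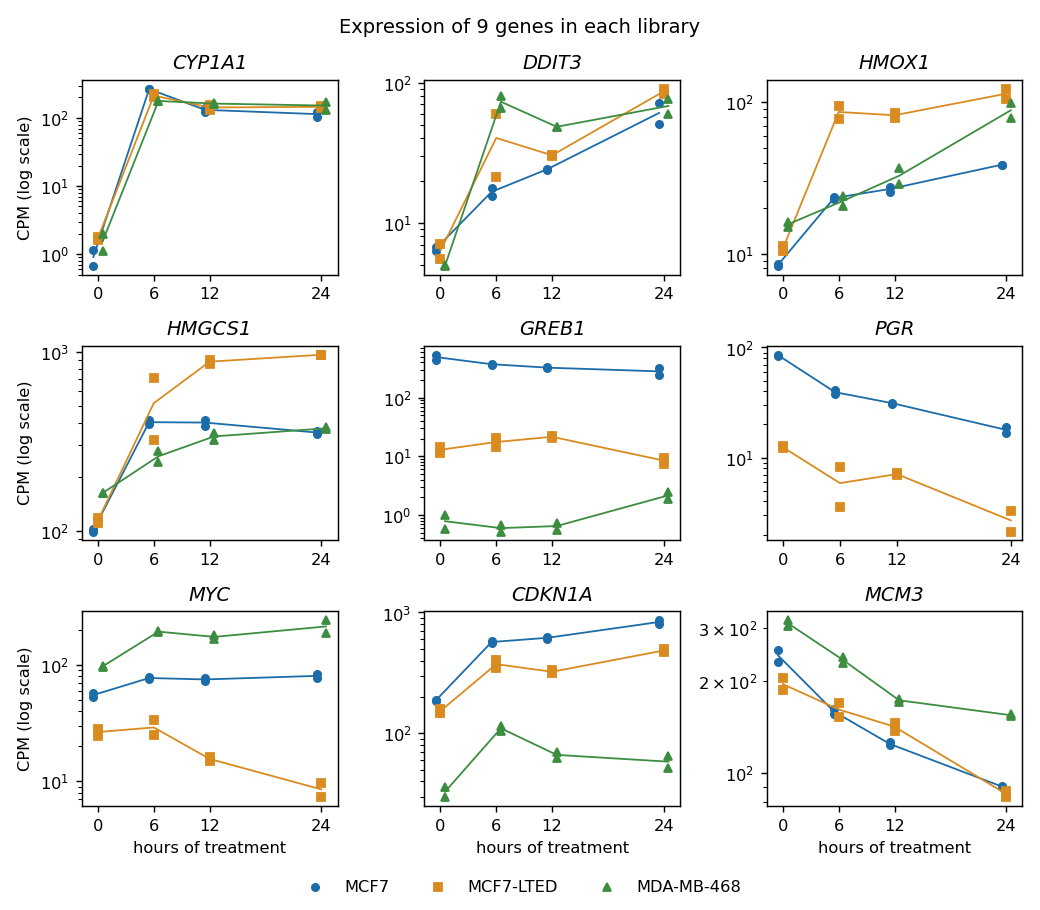
CPM of 9 genes in each library against hours of glyceollin I, on a log scale. Points are libraries, 2 per group, and lines join the group means.

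In MCF7-LTED cells, CYP1A1, NR1D1, PER1 and DDIT3 were among the named rises at 24 h. CYP1A1 rose from 1.72 ± 0.121 to 146 ± 5.6 CPM (log2 fold change 6.41, SE 0.217, adjusted p = 0.000177), NGFR by 4.75 and RND1 by 3.73. The circadian clock genes NR1D1 (ENSG00000126368, chromosome 17, 40092787 to 40100725) and PER1 (ENSG00000179094, chromosome 17, 8140472 to 8156506) went from 5.34 ± 0.0984 to 126 ± 11.8 CPM (4.56) and from 14.2 ± 0.129 to 335 ± 7.73 CPM (4.56), and the clock repressor CIART (ENSG00000159208, chromosome 1, 150282543 to 150287093) rose by 4.53. RRAGD (ENSG00000025039, chromosome 6, 89364636 to 89412270), a GTPase of lysosomal nutrient sensing, rose by 4.03 and the stress factor DDIT3 (ENSG00000175197, chromosome 12, 57516588 to 57521737) from 6.34 ± 1.1 to 86.8 ± 5.28 CPM (3.78, SE 0.481). The lectin CLEC3A (ENSG00000166509, chromosome 16, 78022515 to 78066761) went from 77.2 ± 10.2 to 4.998 ± 1.96 CPM (-3.95, SE 0.513), and the oxygen sensor EGLN3 (ENSG00000129521, chromosome 14, 33924231 to 34462774, -3.65) and the growth factor binding protein IGFBP3 (ENSG00000146674, chromosome 7, 45912245 to 45921874, -3.48) fell. So did the estrogen-binding receptor GPER1 (ENSG00000164850, chromosome 7, 1082208 to 1093815, -3.25), the fucose transporter SLC35C1 (ENSG00000181830, chromosome 11, 45804072 to 45813015, -3.14), the decoy receptor TNFRSF11B (ENSG00000164761, chromosome 8, 118923557 to 118952200, -2.96) and SFXN2 (-2.74). The antisense gene GPC1-AS1 (ENSG00000218416, chromosome 2, 240449315 to 240456714, -3.28) is uncertain, because the strand setting of the counting was not stated. Of 16017 genes tested, 3469 passed, 1603 higher and 1866 lower (46.2% higher, 27.5% with library totals).

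The fit of MCF7-LTED had the widest spread, with a biological coefficient of variation of 22.9% against 9.54% in MCF7 and 10.3% in MDA-MB-468, and its 2 libraries at 6 h differed most. The SD over genes of their log2 ratio was 0.894, against 0.142 to 0.216 in the other pairs of the line and 0.128 to 0.303 in the other lines. Ribosomal protein genes took 15.3% of the counts in column-1 of that pair and 6.505% in column-3. Of the named genes called at 24 h, 66 of 116 lost their call when some library was left out or another setting was used, without any change of direction. Those of HMGCS1 (adjusted p = 0.0566 and 0.0603) and MYC (adjusted p = 0.0679 and 0.0537) were lost without control column-1 or column-2, that of MYC also without 24 h column-3 (adjusted p = 0.0641), and that of DDIT3 without control column-1 (adjusted p = 0.0539). Over the alternatives these ran 7.97e-28 to 0.0603, 5.11e-12 to 0.0679 and 9.28e-35 to 0.0539. Without column-1 of the 6 h pair, 10282 genes passed at 24 h and 5547 at 6 h, whereas 361 and 2 passed without control column-1 and 363 and 1 without control column-2. None of the called genes turned.

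Estrogen-responsive genes were lower in MCF7-LTED at 24 h despite the deprived medium. ESR1 fell from 923 ± 15.9 to 419 ± 35.2 CPM (log2 fold change -1.14, adjusted p = 0.0332) and PGR from 12.4 ± 0.297 to 2.69 ± 0.794 CPM (-2.201), whereas TFF1 (-0.13, adjusted p = 0.86), GREB1 (-0.61, adjusted p = 0.119) and CCND1 (-0.41, adjusted p = 0.156) did not pass. The call of ESR1 was lost without any 1 of the control, 12 h and 24 h libraries (highest adjusted p = 0.2 without 24 h column-1, 2.4e-13 to 0.2 over the alternatives), and that of PGR without any 1 of the control and 24 h libraries (highest adjusted p = 0.111 without 24 h column-3, 8.52e-12 to 0.111 over the alternatives). Of genes induced through the estrogen receptor, 5 of 48 rose and 21 fell (5 and 22 adjusted over the list alone, camera adjusted p = 9.95e-05, adjusted p = 0.112 with an estimated correlation), with the protease TMPRSS3 (-3.63) and the cytokine receptor IL17RB (-1.83) lower. Of luminal markers, 6 of 15 fell and none rose (6 adjusted over the list alone, camera adjusted p = 0.00157, adjusted p = 0.0928 with an estimated correlation), with NAT1 (-2.37) and the carbonic anhydrase CA12 (-1.22) lower. Of basal markers, 3 of 7 rose and none fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.0499, adjusted p = 0.173 with an estimated correlation). The androgen receptor AR fell (-1.86). Of replication genes, 24 of 55 fell and none rose (28 and 1 adjusted over the list alone, camera adjusted p = 9.19e-07, adjusted p = 0.0551 with an estimated correlation). These included DHFR (-2.21) and MCM3 (-1.198), while MKI67 did not pass (-0.42, adjusted p = 0.492). MYC fell (-1.63) and so did ribosome biogenesis genes, of which 1 of 38 rose and 9 fell (1 and 11 adjusted over the list alone, camera adjusted p = 0.0141, adjusted p = 0.224 with an estimated correlation).

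Sterol synthesis and stress programs rose in MCF7-LTED at 24 h. Of cholesterol genes, 15 of 25 rose and none fell (17 adjusted over the list alone, camera adjusted p = 1.05e-09). HMGCS1 went from 114 ± 5.87 to 962 ± 3.53 CPM (3.07), with MSMO1 (2.93), the feedback gene INSIG1 (2.35) and IDI1 (2.26) higher. Of fatty acid genes, 9 of 22 rose and none fell (12 and 1 adjusted over the list alone, camera adjusted p = 1.68e-05, adjusted p = 0.124 with an estimated correlation). Among them was the lipogenic factor SREBF1 (1.82). Of integrated stress response genes, 17 of 34 rose and none fell (21 and 1 adjusted over the list alone, camera adjusted p = 1.89e-10). Members included the phosphatase subunit PPP1R15A (3.09) and ATF3 (2.76). Of unfolded protein response genes, 9 of 27 rose and none fell (13 adjusted over the list alone, camera adjusted p = 1.75e-05). These included the chaperone HSPA5 (1.36). Of NRF2 targets, 15 of 33 rose and none fell (16 adjusted over the list alone, camera adjusted p = 7.5e-07). HMOX1 rose (3.395) and NQO1 did not pass (0.17, adjusted p = 0.752). Of p53 targets, 10 of 34 rose and none fell (11 adjusted over the list alone, camera adjusted p = 6.01e-05). Members included GDF15 (3.55), GADD45A (3.25) and CDKN1A (1.66). Without column-1 of the 6 h pair these list calls at 24 h held with the preset correlation and not with the estimated one, where the lowest was adjusted p = 0.0801.

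The remaining groups of MCF7-LTED at 24 h passed with the preset correlation alone or not at all. Of immediate early genes, 13 of 36 rose and 3 fell (16 and 4 adjusted over the list alone, camera adjusted p = 0.000174, adjusted p = 0.112 with an estimated correlation), with JUN (3.71) and the phosphatase DUSP1 (2.39) higher. Of aryl hydrocarbon receptor targets, 4 of 13 rose and none fell (5 adjusted over the list alone, camera adjusted p = 0.00033, adjusted p = 0.173 with an estimated correlation). Of autophagy genes, 10 of 39 rose and 3 fell (12 and 3 adjusted over the list alone, camera adjusted p = 0.00474, adjusted p = 0.124 with an estimated correlation). Of FOXO and feedback genes, 13 of 32 rose and 3 fell (15 and 4 adjusted over the list alone, camera adjusted p = 0.00113, adjusted p = 0.267 with an estimated correlation). The death ligand TNFSF10 fell (-4.47). Of hypoxia genes, 12 of 35 rose and 2 fell (15 and 4 adjusted over the list alone, camera adjusted p = 0.0099, adjusted p = 0.173 with an estimated correlation). Of NF-kB genes, 6 of 17 rose and none fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.0242, adjusted p = 0.13 with an estimated correlation). Of histone genes, 12 of 24 rose and 1 fell (13 and 2 adjusted over the list alone, camera adjusted p = 4.87e-05, adjusted p = 0.13 with an estimated correlation). Of metallothionein genes, 3 of 5 rose and none fell (4 adjusted over the list alone, camera adjusted p = 0.00534, adjusted p = 0.112 with an estimated correlation). Of genes of the mitochondrial genome, 1 of 13 rose and 5 fell (1 and 5 adjusted over the list alone, camera adjusted p = 0.0499, adjusted p = 0.598 with an estimated correlation). The lists of apoptosis, interferon, TGF-beta, LXR, heat shock, oxidative phosphorylation, receptor and mitosis genes did not pass (lowest camera adjusted p = 0.0829), although BCL2 fell (-3.61). No ribosomal protein gene passed alone although the list did by camera (adjusted p = 0.00374, adjusted p = 0.698 with an estimated correlation).

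Cholesterol synthesis genes were among the early rises of MCF7-LTED. Of genes with a mean of at least 3 log2 CPM, CYP1A1 (6.96), MT1X (4.46), RELB (ENSG00000104856, chromosome 19, 45001430 to 45038198, 3.96) and NGFR (3.899) rose furthest at 6 h, and CLEC3A (-2.94), the neuronal membrane gene SLITRK6 (ENSG00000184564, chromosome 13, 85792787 to 85806683, -2.36), SOX2 (-2.35) and the protocadherin PCDH10 (ENSG00000138650, chromosome 4, 133149315 to 133208606, -2.32) fell furthest. Of cholesterol genes at 6 h, 14 of 25 rose and none fell (17 adjusted over the list alone, camera adjusted p = 3.62e-08). Of interferon genes, 8 of 31 rose and none fell (15 adjusted over the list alone, camera adjusted p = 3.01e-05). The immunoproteasome subunit PSMB9 rose (4.496). Of mitosis genes, 1 of 54 rose and 5 fell (1 and 20 adjusted over the list alone, camera adjusted p = 1.76e-07), with ASPM (-1.68) and the kinase PLK1 (-0.76) lower. The 6 h count was 964 genes (582 higher, 382 lower, 60.4% higher, 39.6% with library totals). Each of the 82 named genes called at 6 h lost its call when only the compared libraries were fitted. Without column-1, the lists of interferon genes (adjusted p = 0.124) and mitosis genes (adjusted p = 0.088) lost their calls with an estimated correlation and cholesterol genes (adjusted p = 0.048) kept theirs. Of NF-kB genes at 6 h, 8 of 17 rose and none fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.000429, adjusted p = 0.0555 with an estimated correlation). At 12 h 1279 genes passed (666 higher, 613 lower, 52.1% higher, 34.5% with library totals), and the count fell to 1 without control column-2. HMGCS1 stood at 2.94 and DDIT3 at 2.26, with adjusted p of 1.09e-24 to 0.175 and 1.07e-15 to 0.252 over the alternatives. Between 6 and 24 h 750 genes differed, 271 higher and 479 lower at 24 h (1958 with DESeq2). The count ran from 0 by edgeR without control column-2 (3424 at unadjusted p under 0.05) to 10632 without 6 h column-3. Of ribosome biogenesis genes, 10 of 38 were lower and none was higher (17 adjusted over the list alone, camera adjusted p = 6.09e-08, adjusted p = 0.0857 with an estimated correlation).

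In MDA-MB-468 cells, which lack estrogen receptor alpha, 24 h of glyceollin I raised CYP1A1, the chemokine CXCL8 and the stress keratins. CYP1A1 went from 1.53 ± 0.626 to 152 ± 28.5 CPM (log2 fold change 6.597, SE 0.222, adjusted p = 5.9e-09), and the chemokine CXCL8 (ENSG00000169429, chromosome 4, 73740506 to 73743716), which encodes interleukin-8, from 1.08 ± 0.414 to 47.9 ± 2.89 CPM (5.49, SE 0.191). The stress keratins KRT6A (ENSG00000205420, chromosome 12, 52487174 to 52493257, 4.89) and KRT6B (ENSG00000185479, chromosome 12, 52446651 to 52452126, 4.69) rose, and which of the near-identical pair supplied the reads is uncertain. The secreted factor IGFL1 (ENSG00000188293, chromosome 19, 46229752 to 46231243, 4.1), the kinase PIM1 (ENSG00000137193, chromosome 6, 37170203 to 37175426, 4.08), DDIT3 (3.78) and RND1 (3.67) followed. The soluble interleukin-22 receptor IL22RA2 (ENSG00000164485, chromosome 6, 137143820 to 137173648) went from 44.3 ± 4.43 to 2.19 ± 0.255 CPM (-4.33, SE 0.175), and the calcium-binding gene S100A7A (ENSG00000184330, chromosome 1, 153416524 to 153423225, -4.16) and the carboxypeptidase CPA4 (ENSG00000128510, chromosome 7, 130293134 to 130324180, -3.34) fell, S100A7A being uncertain because of its relative S100A7. The nuclear receptor coactivator NCOA5 (ENSG00000124160, chromosome 20, 46060985 to 46089952, -3.09), the replication-linked protease FAM111B (ENSG00000189057, chromosome 11, 59107185 to 59127410, -3.01), the matrix gene VWA1 (ENSG00000179403, chromosome 1, 1434861 to 1442882, -2.76) and the noncoding genes LINC01819 (-3.25) and MIR1915HG (-2.85) fell as well. Of 15874 genes tested, 8502 passed, 4296 higher and 4206 lower (50.5% higher, 37.8% with library totals), 1614 and 1809 of them at least 2-fold.

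Stress, inflammatory and detoxification groups rose in MDA-MB-468 at 24 h. Of integrated stress response genes, 33 of 37 rose and 1 fell (33 and 1 adjusted over the list alone, camera adjusted p = 2.1e-12). Members included asparagine synthetase ASNS (3.31) and the mTORC1 inhibitor DDIT4 (2.97). Of unfolded protein response genes, 25 of 28 rose and none fell (26 adjusted over the list alone, camera adjusted p = 1.55e-10, adjusted p = 0.0685 with an estimated correlation). HSPA5 went from 440.2 ± 2.86 to 2261 ± 304 CPM (2.36). Of NRF2 targets, 27 of 35 rose and 1 fell (27 and 1 adjusted over the list alone, camera adjusted p = 2.86e-08). Among them were the aldo-keto reductase AKR1C2 (2.17), HMOX1 (2.505) and NQO1 (0.64). Of NF-kB genes, 22 of 25 rose and none fell (23 adjusted over the list alone, camera adjusted p = 5.11e-12, adjusted p = 0.0685 with an estimated correlation). Members included the apoptosis inhibitor BIRC3 (3.23). Of immediate early genes, 24 of 35 rose and 2 fell (25 and 2 adjusted over the list alone, camera adjusted p = 6.93e-07, adjusted p = 0.202 with an estimated correlation). Of aryl hydrocarbon receptor targets, 11 of 15 rose and none fell (11 adjusted over the list alone, camera adjusted p = 4.64e-06, adjusted p = 0.175 with an estimated correlation). These included TIPARP (2.59).

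Other groups of MDA-MB-468 passed with the preset correlation alone or not at all. Of metallothionein genes, 6 of 7 rose and none fell (7 adjusted over the list alone, camera adjusted p = 3.49e-05, adjusted p = 0.0685 with an estimated correlation). Among them was MT1X (3.35). Of heat shock genes, 11 of 20 rose and 2 fell (12 and 2 adjusted over the list alone, camera adjusted p = 0.021, adjusted p = 0.251 with an estimated correlation). Members included CRYAB (1.503). Of autophagy genes, 17 of 39 rose and 5 fell (18 and 5 adjusted over the list alone, camera adjusted p = 0.00594, adjusted p = 0.251 with an estimated correlation). Of cholesterol genes, 18 of 26 rose and 3 fell (18 and 4 adjusted over the list alone, camera adjusted p = 0.000395, adjusted p = 0.165 with an estimated correlation). These included HMGCS1 (1.201) and MSMO1 (1.59), while fatty acid genes did not shift as a list (camera adjusted p = 0.524) and SREBF1 fell (-1.29). Of basal markers, 8 of 15 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.000748, adjusted p = 0.441 with an estimated correlation). Of luminal markers, 2 of 12 rose and 5 fell (2 and 6 adjusted over the list alone, camera adjusted p = 0.2), with FOXA1 (-0.65) lower. Of p53 targets, 14 of 31 rose and 6 fell (14 and 6 adjusted over the list alone, camera adjusted p = 0.0642), with CDKN1A (0.82), GADD45A (2.92) and FAS (1.88) up.

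Replication genes fell in MDA-MB-468 while several groups split in both directions. Of replication genes at 24 h, 3 of 55 rose and 34 fell (3 and 35 adjusted over the list alone, camera adjusted p = 5.47e-08, adjusted p = 0.0685 with an estimated correlation). Among them were DHFR (-1.797), the polymerase subunit POLA1 (-1.8) and ribonucleotide reductase RRM2 (-1.601). Of mitosis genes, 11 of 54 rose and 16 fell (11 and 16 adjusted over the list alone, camera adjusted p = 0.715), with the mitotic regulator FOXM1 (-1.02) and MKI67 (-0.51) lower. MYC rose (1.14). Of ribosome biogenesis genes, 20 of 38 rose and 7 fell (21 and 7 adjusted over the list alone, camera adjusted p = 0.0801). Of ribosomal protein genes, 39 of 55 rose and none fell (41 adjusted over the list alone, camera adjusted p = 6.65e-07, adjusted p = 0.633 with an estimated correlation). Of genes on the estrogen list, 17 of 44 rose and 11 fell (17 and 11 adjusted over the list alone, camera adjusted p = 0.633), and their median moved from 0.0434 to -0.11 with library totals. The acute phase gene SERPINA3 (5.62), the growth factor AREG (2.52) and GREB1 (1.43) rose, ESR1 did not pass (-0.1002, adjusted p = 0.774), and PGR and TFF1 had too few counts to be tested. CCND1 rose (0.33) but not with library totals (adjusted p = 0.146, 0.00699 to 0.146 over the alternatives), nor without control column-2 (adjusted p = 0.0501) or column-3 (adjusted p = 0.0877). MKI67 lost its call without control column-2 (adjusted p = 0.199), control column-3 (adjusted p = 0.0546) or 24 h column-2 (adjusted p = 0.201, 3.36e-14 to 0.201 over the alternatives). GREB1 lost it without control column-3 (adjusted p = 0.0502, 0.00068 to 0.0502 over the alternatives). The lists of hypoxia, interferon, apoptosis, LXR, oxidative phosphorylation, FOXO, TGF-beta, histone, mitochondrial and receptor genes did not pass camera (lowest camera adjusted p = 0.0805). The hypoxia gene CA9 (-2.36) and the histone gene H2AC6 (-1.65) were lower.

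Inflammatory and ER stress transcripts of MDA-MB-468 were raised by 6 h. CXCL8 reached 152 ± 5.69 CPM (log2 fold change 7.15, SE 0.192, adjusted p = 1.18e-09), CYP1A1 stood at 6.82, the hair follicle keratin KRT75 (ENSG00000170454, chromosome 12, 52424070 to 52434525) at 4.48 and IGFL1 at 4.45. The chaperone HSPA8 (ENSG00000109971, chromosome 11, 123057489 to 123063230) went from 2409 ± 140 to 625 ± 8.35 CPM (-1.95), and NCOA5 (-2.61), FAM111B (-2.05) and FAM172A (ENSG00000113391, chromosome 5, 93618069 to 94111699, -1.93) fell. Of unfolded protein response genes at 6 h, 27 of 28 rose and none fell (27 adjusted over the list alone, camera adjusted p = 7.07e-21). Members included HSPA5 (2.83). Of integrated stress response genes, 31 of 37 rose and none fell (32 adjusted over the list alone, camera adjusted p = 5.63e-18). Of NF-kB genes, 22 of 25 rose and none fell (23 adjusted over the list alone, camera adjusted p = 6.78e-21). These included CXCL1 (5.298) and TNFAIP3 (3.58). Of mitosis genes, 33 of 54 fell and none rose (34 adjusted over the list alone, camera adjusted p = 4.88e-09, adjusted p = 0.111 with an estimated correlation). Among them were ASPM (-1.36), the kinesin KIF20A (-1.16) and MKI67 (-1.14). At 6 h 5029 genes passed (2608 higher, 2421 lower, 51.9% higher, 39.8% with library totals) and at 12 h 6488 (3347 higher, 3141 lower, 51.6% higher, 41.5% with library totals), with CYP1A1 at 6.695. These counts were as low as 2730 without MDA-MB-468 control column-2 and 4102 without MDA-MB-468 control column-2. Set directly against 6 h, 5271 genes differed at 24 h, 2558 higher and 2713 lower (48.5% higher, 39.4% with library totals). Mitosis genes were higher again, and 29 of 54 were higher and 1 was lower (30 and 2 adjusted over the list alone, camera adjusted p = 1.42e-07, adjusted p = 0.269 with an estimated correlation). Of cholesterol genes, 18 of 26 were higher and 1 was lower (18 and 1 adjusted over the list alone, camera adjusted p = 1.48e-06, adjusted p = 0.216 with an estimated correlation). Of unfolded protein response genes, 3 of 28 were higher and 14 were lower (4 and 15 adjusted over the list alone, camera adjusted p = 0.00472, adjusted p = 0.439 with an estimated correlation).

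**Figure D3:**
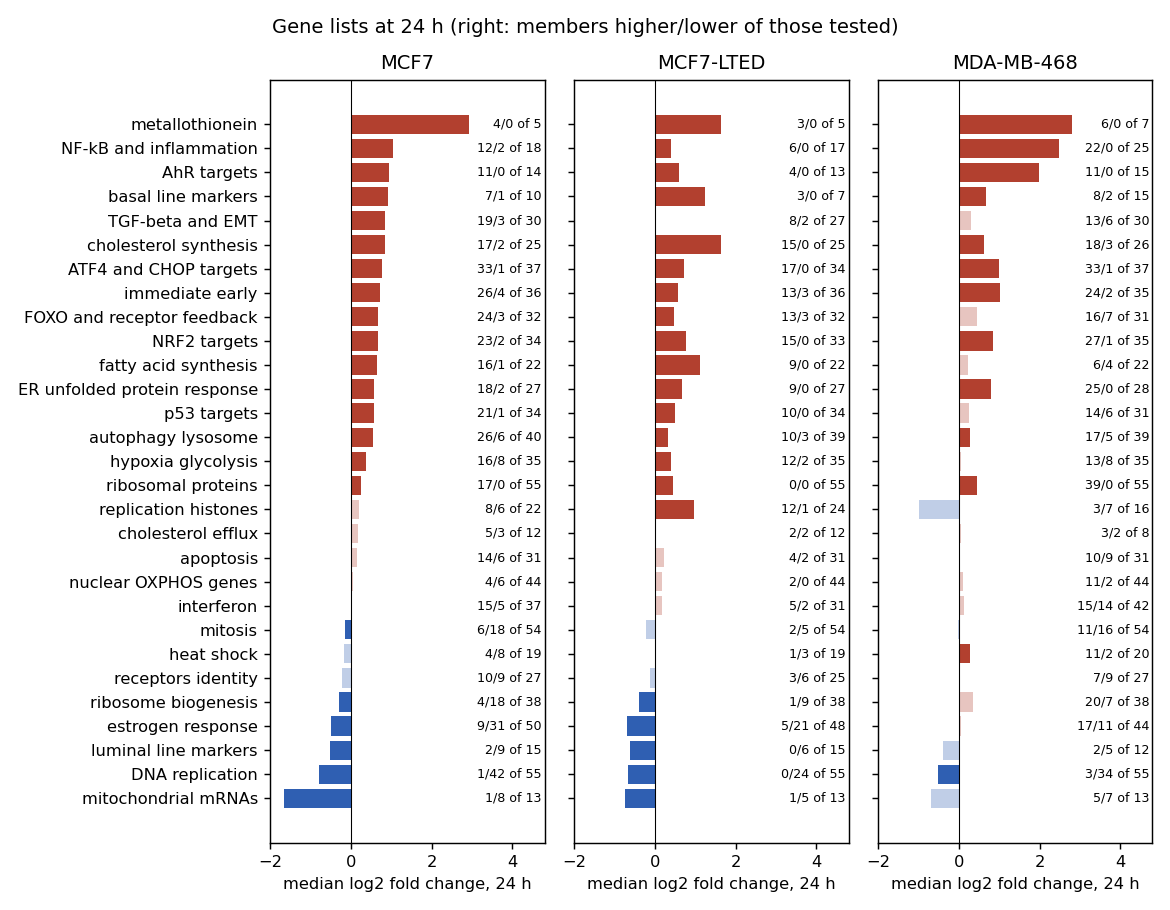
Median log2 fold change of each gene list at 24 h against the untreated control in each line. Dark bars passed camera at adjusted p under 0.05 with a correlation of 0.01, and the numbers at the right give members higher and lower of those tested.

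Before treatment, MCF7-LTED differed from MCF7 in estrogen targets and interferon genes. ESR1 was higher, 923 ± 15.9 against 349 ± 22.6 CPM (log2 difference 1.45, SE 0.233, adjusted p = 0.000183), whereas the estrogen target GREB1 (ENSG00000196208, chromosome 2, 11482341 to 11642788) was lower, 12.9 ± 2.3 against 494 ± 72 CPM (-5.21), with PGR (-2.73), TFF1 (-1.13) and MYC (-1.01). BRINP3 (ENSG00000162670, chromosome 1, 190097662 to 190478404, 5.21), TNFRSF11B (3.91), the secreted gene CRISP3 (3.76), the glutamate receptor GRIK2 (3.48), the glycine receptor GLRA3 (3.28) and PARM1 (3.26) were the most raised of the genes that met the abundance limit. The ephrin receptor EPHA4 (ENSG00000116106, chromosome 2, 221418027 to 221574202, -4.22), the collagen COL5A1 (-4.05), the matricellular gene CCN5 (-4.04), IGSF1 (-3.95) and the desmosomal cadherin DSG2 (-3.85) were the most reduced after GREB1, and CYP1A1 (0.94) and NQO1 (0.92) were higher. Of estrogen-induced genes, 3 of 50 were higher and 28 were lower (4 and 29 adjusted over the list alone, camera adjusted p = 5.17e-14). Of interferon genes, 1 of 43 was higher and 24 were lower (1 and 26 adjusted over the list alone, camera adjusted p = 2.59e-07). Of replication genes, 20 of 55 were lower and none was higher (26 adjusted over the list alone, camera adjusted p = 2.3e-06). Of ribosome biogenesis genes, 19 of 38 were lower and none was higher (28 adjusted over the list alone, camera adjusted p = 1.97e-09). Of histone genes, 16 of 25 were higher and none was lower (18 adjusted over the list alone, camera adjusted p = 1.1e-09). Of TGF-beta genes, 2 of 33 were higher and 13 were lower (3 and 14 adjusted over the list alone, camera adjusted p = 0.000635), and this last call was lost without column-1 of the 6 h pair (adjusted p = 0.0621 with an estimated correlation). In all, 4114 of 18669 genes differed, 1833 higher and 2281 lower in MCF7-LTED (2446 without MCF7-LTED control column-1 to 6810 without MCF7-LTED 6 h column-1).

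The calls of the 2 estrogen receptor-positive lines overlapped at 24 h. MCF7-LTED and MCF7 shared 1395 higher and 1482 lower genes, where independent lists would share 399 and 431, and the log2 fold changes correlated at r = 0.827. MDA-MB-468 shared 2181 higher and 1986 lower genes with MCF7 (independent lists 1029 and 906, r = 0.596), and 995 and 1055 with MCF7-LTED (independent lists 403 and 392, r = 0.607). At 6 h, with the MCF7-LTED pair that differed most, r was 0.399, 0.494 and 0.477 in turn. Among genes called in both lines, 7 of 2884 went opposite ways in MCF7-LTED and MCF7, against 473 of 4640 in MDA-MB-468 and MCF7 and 148 of 2198 in MDA-MB-468 and MCF7-LTED. Each line had its own controls. CYP1A1, DDIT3, HMOX1, CDKN1A and HMGCS1 passed and rose in every line at 24 h.

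Tested directly, the response of MCF7-LTED at 24 h departed from that of MCF7 in 158 genes, 69 with a higher and 89 with a lower log2 fold change (48 without MCF7-LTED control column-2 to 807 without MCF7-LTED 6 h column-3, 436 with DESeq2). Immediate early and AP-1 genes did not pass as a list, as 3 of 36 passed upward and 1 passed downward (4 and 6 adjusted over the list alone, camera adjusted p = 0.745). Among them, FOS fell in MCF7 (-2.63) and did not pass in MCF7-LTED (0.11, adjusted p = 0.734), and JUN rose by 3.71 in MCF7-LTED and 1.29 in MCF7. MYC rose in MCF7 (0.55) and fell in MCF7-LTED (-1.63), and TIMP3 rose in MCF7 (0.83) and fell in MCF7-LTED (-1.49). Cholesterol genes rose further in MCF7-LTED, as 7 of 26 passed upward and none passed downward (13 adjusted over the list alone, camera adjusted p = 6.95e-13), with log2 differences of 1.44 for IDI1 and 1.16 for MSMO1. Of histone genes, 3 of 25 passed upward and none passed downward (12 adjusted over the list alone, camera adjusted p = 1.96e-12). At 6 h, with the MCF7-LTED pair that differed most, 517 genes differed and at 12 h 43, and no library was left out there.

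MDA-MB-468 answered differently from MCF7 in 2080 genes at 24 h (867 higher, 1213 lower) and from MCF7-LTED in 2147 (902 higher, 1245 lower, 42.01% higher, 56.4% with library totals). These counts ran from 1241 without MDA-MB-468 control column-2 to 4241 without MCF7-LTED 6 h column-1 and from 1269 without MCF7-LTED control column-1 to 4165 without MCF7-LTED 6 h column-1. Estrogen-induced genes responded more upward in MDA-MB-468 than in MCF7, as 16 of 50 passed upward and 3 passed downward (21 and 5 adjusted over the list alone, camera adjusted p = 2.89e-08), with SERPINA3 (4.68) and the hormone STC2 (1.998). They did so too against MCF7-LTED, as 18 of 50 passed upward and 2 passed downward (20 and 2 adjusted over the list alone, camera adjusted p = 1.7e-07). NF-kB genes responded more against MCF7, as 5 of 25 passed upward and 1 passed downward (8 and 1 adjusted over the list alone, camera adjusted p = 5.91e-08). Against MCF7-LTED they did so too, as 8 of 25 passed upward and none passed downward (9 adjusted over the list alone, camera adjusted p = 1.41e-08). Members included the early response gene IER3 (2.44). Ribosome biogenesis genes differed in the same way, 10 of 38 passed upward and none passed downward (11 and 1 adjusted over the list alone, camera adjusted p = 3.21e-06) against MCF7 and 9 of 38 passed upward and none passed downward (13 adjusted over the list alone, camera adjusted p = 1.1e-06) against MCF7-LTED. Against MCF7, unfolded protein response genes responded more, 4 of 28 passed upward and 1 passed downward (8 and 1 adjusted over the list alone, camera adjusted p = 0.000193), as did heat shock genes, 8 of 20 passed upward and 1 passed downward (10 and 1 adjusted over the list alone, camera adjusted p = 1.25e-05). These included the co-chaperone BAG3 (1.82). Against MCF7-LTED, sterol genes responded less, 14 of 26 passed downward and none passed upward (17 adjusted over the list alone, camera adjusted p = 2.97e-09), as did fatty acid genes, 9 of 22 passed downward and none passed upward (9 adjusted over the list alone, camera adjusted p = 1.1e-06), with SREBF1 (-3.16). Histone genes did as well, 13 of 25 passed downward and none passed upward (15 adjusted over the list alone, camera adjusted p = 2.7e-08).

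Markers of other cells and of the other line type were summed in each library. Stroma markers summed to 20.6 to 47.6 CPM over the libraries, and in MDA-MB-468, where 6 could be tested, 1 of 6 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.554). Leukocyte markers summed to at most 1.49 CPM in MCF7 and MCF7-LTED, and in MDA-MB-468 to 47.1 and 41.5 CPM in the controls and 19.5 and 20.3 CPM at 24 h, too few of them counted to be tested as a list. The CPM sum includes the monocyte receptor gene CD14, which fell (-0.99). Basal markers summed to 195 and 198 CPM in MCF7 controls and 7140 and 6692 CPM in MDA-MB-468 controls, and luminal markers to 10410 and 10250 CPM against 2956 and 3061 CPM. At 24 h the sums of basal markers were 1049 and 1049 CPM in MCF7 and 12040 and 12940 CPM in MDA-MB-468, and those of luminal markers 7215 and 7504 CPM and 1828 and 2175 CPM.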

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

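None of the tests in this part was chosen after its result was seen, and the adjusted p-values are those of edgeR for genes and of camera with an estimated correlation for lists. Results stand here because the response to glyceollin I differed between lines, or between 24 h and 6 h, in a test of the difference itself. Against 6 h, 3546 genes of MCF7, 750 of MCF7-LTED and 5271 of MDA-MB-468 differed at 24 h. The 24 h responses differed in 158 genes between MCF7-LTED and MCF7, 2080 between MDA-MB-468 and MCF7 and 2147 between MDA-MB-468 and MCF7-LTED. Differences below are log2, the response in the line named first minus that in the other, with 2 libraries in every group.

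Between MCF7-LTED and MCF7 the response differed by 2.73 (adjusted p = 2.68e-06) for FOS, which fell from 31.4 ± 1.29 to 5.08 ± 0.00969 CPM in MCF7. It differed by 2.62 (adjusted p = 0.000137) for the poly(A) polymerase TENT5B, 2.42 (adjusted p = 6.22e-06) for JUN, 2.36 (adjusted p = 0.00103) for the histone gene H2BC11 and 2.24 (adjusted p = 1.28e-05) for the purine phosphorylase PNP. The histone value is uncertain because near-identical copies share reads. Lower responses in MCF7-LTED were -2.33 (adjusted p = 2.89e-07) for TIMP3, -2.18 (adjusted p = 0.000548) for the ER stress factor CREB3L1, -2.18 (adjusted p = 7.82e-05) for MYC, -1.99 (adjusted p = 0.0136) for the mucin MUC5AC and -1.94 (adjusted p = 0.00556) for the netrin NTN4. CREB3L1, MUC5AC and NTN4 rose in MCF7 (1.71, 2.35 and 1.55) and did not pass in MCF7-LTED. HMOX1 rose further in MCF7-LTED by 1.204 (adjusted p = 0.00679). Of 33 named calls of this pair, 23 were lost under some alternative, HMOX1 among them. For the pairs below, 36 of 98 and 19 of 90 were, in turn. Cholesterol genes (adjusted p = 5.76e-05) and histone genes (adjusted p = 0.0266) differed as lists.

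Between MDA-MB-468 and MCF7 the response of FOS differed by 3.65 (adjusted p = 2.1e-08), as FOS rose in MDA-MB-468 (1.08). The protease PRSS23 fell in MCF7 (-1.59) and rose in MDA-MB-468 (1.38), a difference of 2.92 (adjusted p = 4.33e-08). FAM43A (2.91) and SMG8 (2.896), a regulator of nonsense-mediated decay, rose in MDA-MB-468 (2.69 and 3.02), and the adaptor AFAP1L2 differed by 2.68 (adjusted p = 8.93e-06). Lower responses in MDA-MB-468 were -3.36 for KRT86, which overlaps KRT81 and is uncertain, -2.99 for the mucin MUC5B, -2.97 for the epithelial factor GRHL3, -2.85 for the actin regulator RAPH1 and -2.81 for CRISP3, each with adjusted p under 0.05. GREB1 rose in MDA-MB-468 and fell in MCF7, a difference of 2.18 (adjusted p = 0.000966), and CDKN1A rose less in MDA-MB-468 by -1.39 (adjusted p = 0.000107). As lists, estrogen-induced genes (adjusted p = 0.00063), unfolded protein response (adjusted p = 0.0156), heat shock (adjusted p = 0.0377), NF-kB (adjusted p = 0.000724) and ribosome biogenesis genes (adjusted p = 0.0129) differed.

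Between MDA-MB-468 and MCF7-LTED the response differed by 4.1 for the ubiquitin ligase adaptor KCTD5, which rose in MDA-MB-468 (4.52), and by 3.94 for TNFSF10, which fell in MCF7-LTED (-4.47). The matrix gene TINAGL1 (3.93) and the transcription factor SIM1 (3.88) rose in MDA-MB-468 and fell in MCF7-LTED, and TMPRSS3 (3.84) fell in MCF7-LTED. TENT5B (-4.55), JUN (-4.26) and the matricellular gene CCN1 (-4.09) rose in MCF7-LTED and fell in MDA-MB-468, and CIART (-3.81) and RRAGD (-3.59) rose in MCF7-LTED by more. GREB1 (1.99 (adjusted p = 0.00217)), CCND1 (0.69 (adjusted p = 0.0166)) and MYC (2.72 (adjusted p = 7.78e-07)) responded more upward in MDA-MB-468. CDKN1A (-0.89 (adjusted p = 0.00364)), HMOX1 (-0.94 (adjusted p = 0.00496)) and HMGCS1 (-1.92 (adjusted p = 0.00071)) rose less in MDA-MB-468 than in MCF7-LTED. As lists, estrogen-induced (adjusted p = 0.00473), cholesterol (adjusted p = 0.000311), fatty acid (adjusted p = 0.0187), NF-kB (adjusted p = 0.000417), ribosome biogenesis (adjusted p = 0.0107) and histone genes (adjusted p = 0.0165) differed.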

How the results depend on the processing

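The MCF7-LTED fits without column-1 of the 6 h pair were added after its counts had been seen, the replicate block was added later, and all other fits were planned. Counts of changed genes stayed within 1.5 times under every setting not named in this part, no called gene turned direction in any of them, and the cause of the shifts was not tested. In MCF7-LTED at 6 h, 964 genes became 1849 with DESeq2, 626 with library totals, 3307 with no filter, 1989 in the authors' table and 0 by edgeR with only the compared libraries (2073 at unadjusted p under 0.05). At 12 h, 1279 became 2284 with no filter and 8826 with only the compared libraries, and at 24 h 3469 became 9864 with those. For 24 h against 6 h, 750 became 1958 with DESeq2, 443 with library totals, 3261 with no filter and 0 by edgeR with only the compared libraries (1831 at unadjusted p under 0.05). The 158 genes of MCF7-LTED minus MCF7 became 436 with DESeq2, 248 with no filter and 85 with these lines alone, and the 2080 of MDA-MB-468 minus MCF7 3679 with these lines alone. With library totals the median of all genes stood at 24 h at -0.14 in MCF7, -0.21 in MCF7-LTED and -0.15 in MDA-MB-468, at -0.23 and -0.11 in MCF7-LTED at 6 and 12 h and at -0.11 in MCF7 for 24 h against 6 h.

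Leaving out each library in turn, with the lone library of its group assumed to vary like the other groups, gave 2733 to 6925, 4222 to 7980 and 6897 to 8008 genes in MCF7 at 6, 12 and 24 h and 953 to 4561 for 24 h against 6 h. It gave 2730 to 5196, 4102 to 6919, 6386 to 8973 and 3654 to 5182 in MDA-MB-468 and 1 to 11016, 1 to 8387, 361 to 10292 and 0 to 10632 in MCF7-LTED. For the differences it gave 48 to 807 for MCF7-LTED minus MCF7, 1241 to 4241 for MDA-MB-468 minus MCF7, 1269 to 4165 for MDA-MB-468 minus MCF7-LTED and 2446 to 6810 for the untreated lines. Counts moved by more than 1.5 times were, in MCF7, 2733 without MCF7 6 h column-2, 2813 without MCF7 6 h column-3 at 6 h, 4222 without MCF7 12 h column-2, 4261 without MCF7 12 h column-3 at 12 h and 953 without MCF7 6 h column-3, 1114 without MCF7 6 h column-2 for 24 h against 6 h. In MDA-MB-468 they were 2730 without MDA-MB-468 control column-2, 3049 without MDA-MB-468 control column-3 at 6 h and 4102 without MDA-MB-468 control column-2, 4108 without MDA-MB-468 control column-3 at 12 h. Each library of MCF7-LTED moved every count of that line, and in the order control, 6 h, 12 h and 24 h the counts without it were 2 and 1, 5547 and 11016, 85 and 52, 77 and 103 at 6 h, 2 and 1, 8356 and 8387, 1 and 9, 128 and 238 at 12 h, 361 and 363, 10282 and 10292, 1894 and 1803, 602 and 431 at 24 h and 3 and 0, 6385 and 10632, 0 and 0, 0 and 0 for 24 h against 6 h. The counts of 0 came from edgeR with 2234 to 3610 genes at unadjusted p under 0.05, where DESeq2 gave 1958 on all 8 libraries. For MCF7-LTED minus MCF7 they were 48 without MCF7-LTED control column-2, 50 without MCF7-LTED control column-1, 55 without MCF7 24 h column-2, 58 without MCF7-LTED 24 h column-1, 66 without MCF7-LTED 24 h column-3, 70 without MCF7 control column-1, 91 without MCF7 control column-3, 805 without MCF7-LTED 6 h column-1, 807 without MCF7-LTED 6 h column-3. For MDA-MB-468 minus MCF7 they were 1241 without MDA-MB-468 control column-2, 1320 without MDA-MB-468 24 h column-2, 1323 without MCF7 24 h column-2, 1338 without MDA-MB-468 control column-3, 1356 without MCF7 control column-1, 4228 without MCF7-LTED 6 h column-3, 4241 without MCF7-LTED 6 h column-1. For MDA-MB-468 minus MCF7-LTED they were 1269 without MCF7-LTED control column-1, 1343 without MCF7-LTED 24 h column-3, 1369 without MDA-MB-468 control column-2, 1384 without MCF7-LTED control column-2, 1392 without MDA-MB-468 control column-3, 4144 without MCF7-LTED 6 h column-3, 4165 without MCF7-LTED 6 h column-1, and for the untreated lines 2446 without MCF7-LTED control column-1, 2480 without MCF7-LTED control column-2, 2666 without MCF7 control column-1, 6808 without MCF7-LTED 6 h column-3, 6810 without MCF7-LTED 6 h column-1.

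Genes that had not passed changed sign in places. With library totals MKI67 stood at -0.13 in MCF7 at 24 h (-0.00777 with a mean of 50 counts, -0.3972 to 0.53 with libraries left out) and at -0.0417 in MCF7-LTED at 12 h (-0.012 to 0.13). In MCF7-LTED, CCND1 at 12 h stood at -0.0608 (-0.0256 to 0.1033), NQO1 at 24 h at -0.0476 and MYC at 6 h at -0.12 (-0.21 to 0.32). ESR1 in MCF7 at 6 h stood at 0.00904 with no filter and 0.0007394 with a mean of 50 counts (-0.0741 to 0.0559). In MDA-MB-468 with libraries left out, GREB1 ran from -0.74 to 0.04998 at 6 h and -0.63 to 0.16 at 12 h, and ESR1 from -0.25 to 0.0495 at 24 h. Gene lists called by camera in MCF7-LTED at 24 h all lost their call with an estimated correlation once column-1 at 6 h was left out (p53, adjusted p = 0.0801). The planned block on the replicate numbers of the titles was not run, because these cannot be matched to columns.

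A replicate block on the column number, whose meaning is not stated, was fitted instead. Where groups of a line shared both numbers, their differences between columns correlated at 0.0326 to 0.154, so the numbers were not taken to pair the libraries. With the block 3436, 4772 and 6533 genes passed in MCF7 at 6, 12 and 24 h, 6809, 8611 and 9669 in MDA-MB-468 and 1, 1 and 518 in MCF7-LTED. For 24 h against 6 h 4292, 7150 and 0 passed, the last by edgeR with 3705 at unadjusted p under 0.05, where DESeq2 without the block gave 1958. The differences at 24 h held 16 for MCF7-LTED minus MCF7, 915 for MDA-MB-468 minus MCF7 and 1178 for MDA-MB-468 minus MCF7-LTED, and the untreated lines 1978. MKI67, not called without the block, stood at -0.0311, -0.12 and -0.53 in MCF7 at 6, 12 and 24 h, where the last passed (adjusted p = 0.0322, 0.0322 to 1 over the alternatives), and at -0.26 in MCF7-LTED at 12 h. TFF1 in MCF7-LTED stood at 0.23 at 12 h and 0.0433 at 24 h.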

Other observations

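Tests chosen only after their result was seen were the transcript length test of the MCF7-LTED pair, the test of the whole mitochondrial genome, the matched tests of single-exon genes and the reading of the 12 h response for column-3, and the clock genes were picked after their values had been seen. No clock list was tested, and PER1, NR1D1, DBP, CIART and BHLHE40 rose in all 3 lines at 24 h. Given for MCF7 first, MCF7-LTED next and MDA-MB-468 last, the log2 fold changes were 3.01, 4.56 and 3.32 for the period gene PER1, 3.02, 4.56 and 2.96 for the nuclear receptor NR1D1, 2.37, 3.15 and 1.27 for the clock output factor DBP, 2.68, 4.53 and 0.77 for CIART and 1.67, 3.05 and 1.805 for the repressor BHLHE40. PER2 rose in MCF7 (0.66), fell in MDA-MB-468 (-0.47) and did not pass in MCF7-LTED (0.61, edgeR adjusted p = 0.0725), and CRY1 rose in MCF7 (0.3956) and did not pass in MCF7-LTED (0.34, edgeR adjusted p = 0.386) or MDA-MB-468 (0.12, edgeR adjusted p = 0.464). The labels give no untreated cells matched to 6, 12 or 24 h, so hours in culture and glyceollin I cannot be parted here.

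The pair of MCF7-LTED libraries at 6 h stood apart, with an SD over genes of its log2 ratio of 0.894 against 0.128 to 0.303 in the other 11 pairs. Its log2 ratio followed transcript length with a Spearman rho of -0.6732, where the other pairs reached 0.665 in size, and with a slope of -0.622 per doubling of length, where they reached 0.1851, so a length bias in 1 library may contribute. It was not the whole difference, since the SD after removal of a trend in length and GC content was 0.6507 against at most 0.2361 elsewhere. MDA-MB-468 RNA was excluded, as its genes reached 0.05562% of their level there. A stronger or later response to the compound in either column stays open. The rho of column-1 over column-3 with the 12 h response, -0.2192, kept the length trend and cannot decide. Other causes stay open.

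Of the 13 messenger RNAs of the mitochondrial genome, 8 fell, 1 rose and 4 did not pass in MCF7 at 24 h, and the call of the list was lost with an estimated correlation (adjusted p = 0.255). Falls included MT-ND1 (-1.83), MT-ND2 (-2.06) and MT-CO3 (-2.298). Lower output of the whole genome stays open: the ribosomal RNA MT-RNR2 rose by 1.411 (SE 0.121), but that rise is part of the pattern and its count depends on tails too. Nuclear copies did not rise to match, gaining -1.551% of what the mitochondrial genes lost. The read filters are not stated, so a loss of reads that fit both places stays open. A loss of short transcripts is less likely, not excluded. In the same length range, 230 abundant nuclear mRNAs had a median of 0.08258 (quartiles -0.19 and 0.2949). A change in poly(A) tails, on which the library kit depends, was not tested, nor was any other biological explanation.

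Protein-coding genes with fewer exons fell further at 24 h, with medians of -0.32, -0.227 and -0.446 in MCF7, its LTED line and MDA-MB-468 for 1 exon, -0.161, -0.159 and -0.22 for 2 and 0.0376, 0.0476 and 0.0398 for at least 3. Matched on GC content, length and abundance, the difference of 1 exon from at least 3 was -0.293 in MCF7 and -0.543 in MDA-MB-468. It was -0.217 in MCF7-LTED (interval -0.455 to -0.0924). How close the matches were was not tested, so these properties stay open. A test over all lines at once, set out before, would have been undecided. Genomic DNA in the controls was excluded, as olfactory receptor genes carried 0.204% of the median loss. Faster decay or lower transcription of such genes are possible explanations that were not tested.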
